A study of Mus musculus with 15 samples.

How the data were processed

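Polyadenylated RNA was sequenced from 15 mouse adipose libraries in 4 groups. Brown adipose tissue came from newborn pups at postnatal day 0.5, with 4 wild-type libraries and 4 labelled IL-33 knockout. Inguinal white adipose tissue came from weaning-age mice at day 24, with 4 wild-type libraries and 3 labelled knockout, numbered 2 to 4. All carried the C57BL/6 background, per the labels. Tissue and age differ together, so no comparison between the depots can separate them. Nothing in the labels says that the libraries of a group came from separate animals, and p-values then measure only the spread between these libraries, which may be technical.

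Per the labels' protocols, RNA was extracted with TRIsure and a spin-column kit, and libraries were made with the Illumina TruSeq stranded mRNA kit. The submitters' processing notes name TopHat2 2.1.0, featureCounts, Subread, edgeR and the mm9 genome build. The role of each tool, the annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes are therefore uncertain. The deposited values are raw counts per gene, whole numbers with no normalization by the authors. Ensembl gene identifiers name the genes. Of the 37991 identifiers, 32919 were matched to a symbol and 5072 kept their identifier, and 26485 had at least 1 count. The reference annotation was of another build than mm9, so it served only for symbols and for the order of neighbouring genes, and no coordinates are given.

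Total counts ran from 26059635 to 53923009 per library. All 37 mitochondrial gene identifiers had 0 counts in every library, so the list of mitochondrially encoded genes could not be tested. Their reads may be counted elsewhere: 4 pseudogenes matched mitochondrial genes at 95% identity or more over at least 100 bp (blastn 2.17.0), and Gm13340 alone took 6.41% of counts on average. No pair of libraries of the same group agreed within sampling noise, the lowest chi-square per degree of freedom being 14.7. Intervals on counts are exact Poisson intervals at 95% and cover counting error only.

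Each comparison was fitted on its own libraries in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and the quasi-likelihood F-test used robust dispersions. Genes passed at a Benjamini-Hochberg adjusted p below 0.05. The comparisons were labelled knockout against wild type in each depot, the difference between these effects (all 4 groups), and wild-type brown against wild-type inguinal tissue. Calls shared by the depots were counted per direction with a one-sided Fisher exact test. Levels are TMM-scaled counts-per-million values (CPM), given as mean ± SD, except that Il33 per library is given as CPM of the total count. Fold changes are log2 values with a standard error (SE). It was derived as the absolute log2 change divided by the square root of the F statistic. The interval of Nnt and the expected shares of shared signs used it with normal quantiles.

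The 34 gene lists of pathways and cell-type markers, the tests, the alternatives and the rule for naming genes were chosen before the data were examined. Of 747 list entries, 738 matched a gene, 2 of them through an older symbol. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Calls were set beside camera with an estimated correlation and beside fry (limma 3.58.1). The rule named Il33, Il1rl1 and Ucp1 always, then the 10 largest rises and 10 largest falls of each knockout comparison (5 and 5 for the others). These needed an adjusted p below 0.05, at least 1 CPM in the higher group and no overlap between groups, and predicted genes were left out. The rule also took up to 4 members of each list by smallest p. The text names part of what the rule picked. That part was chosen after the values were seen, to limit length and to leave out some of the folds near the detection floor.

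The fitting steps were tested on simulated counts drawn from the means and library sizes of the real libraries, with 67, 67 and 66 genes changed by 1.5, 2 and 4 fold. In brown tissue (15602 genes) 17.9%, 55.2% and 92.4% of them were recovered. In inguinal tissue (15516 genes) the shares were 50.7%, 76.1% and 97.0%. For the difference between depots (16579 genes) they were 8.96%, 37.3% and 72.7%, and for wild-type tissues (15794 genes) 44.8%, 68.7% and 93.9%. Unchanged genes made up 5.98%, 8.59%, 2.47% and 3.50% of the simulated calls of these 4 comparisons.

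The alternatives were DESeq2 size factors, no filter on low counts, a filter at 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom with library quality weights, non-robust dispersions, the replicate number as a block, all 4 groups in 1 fit, and leaving out each library in turn. Removing the mitochondrial-like pseudogenes and the most abundant identifier without a symbol was an alternative chosen after seeing the data. Moving from TMM to DESeq2 size factors shifted the median log2 change by at most 0.01. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.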

Results

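Gene expression was measured by RNA sequencing in 2 adipose depots of wild-type mice and of mice labelled as lacking IL-33, a cytokine released by stressed or damaged cells that acts through the receptor ST2. Brown adipose tissue, which makes heat, was taken at postnatal day 0.5, and inguinal white adipose tissue, which can hold heat-producing beige adipocytes, at day 24. Total counts were 31661512 to 41926108 in the 4 wild-type and 33782634 to 40802095 in the 4 labelled knockout brown libraries. In inguinal tissue they were 26059635 to 53923009 in the 4 wild-type and 30835337 to 38765633 in the 3 labelled knockout libraries. The title of the series asks how IL-33 and ST2 bear on uncoupled respiration, the heat-producing process carried out by the uncoupling protein UCP1.

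Il33 (ENSMUSG00000024810) was measured first, as the check of the labels. In inguinal tissue it stood at 3.44, 4.55, 3.84 and 3.67 counts-per-million (CPM) in wild-type libraries 1 to 4 and at 0.324, 0.434 and 0.0774 CPM in knockout libraries 2 to 4. It fell by 3.73 on the log2 scale (SE 0.36, edgeR adjusted p = 1.25e-05). In brown tissue the wild-type libraries held 1.89, 3.38, 2.02 and 1.77 CPM and the labelled knockout libraries 0.438, 1.66, 1.45 and 0.588 CPM. The brown change of -1.08 (SE 0.44) did not pass (edgeR adjusted p = 0.229, 0.0334 unadjusted). Counts per brown library ran from 15 to 107, and the exact intervals of labelled knockout libraries 2 (1.25 to 2.15 CPM) and 3 (1.08 to 1.90) reached into the wild-type range. All 4 labelled knockout libraries were below all 4 wild-type ones by total count, while after TMM scaling labelled knockout library 2 and wild-type library 4 were level at 1.77 CPM. Il33 therefore leaned toward the brown labels without settling them, and the brown group is called labelled knockout throughout. Which part of Il33 was deleted is not given in the sources used here.

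Ucp1 (ENSMUSG00000031710) rose in inguinal knockout tissue, from 801 ± 200 (SD, n = 4) to 1885 ± 270 CPM (n = 3), a log2 change of 1.24 (SE 0.17, edgeR adjusted p = 0.000382). In brown tissue Ucp1 was 4830 ± 2245 in wild type and 2514 ± 900 CPM in labelled knockout (n = 4 each). That change of -0.94 (SE 0.37) did not pass (edgeR adjusted p = 0.220). The 2 effects differed by 2.15 (SE 0.47, edgeR adjusted p = 0.0147). Il1rl1 (ENSMUSG00000026069), which encodes ST2, did not pass in brown tissue (0.17, SE 0.23, edgeR adjusted p = 0.730) or inguinal tissue (0.26, SE 0.19, edgeR adjusted p = 0.327).

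**Figure D1:**
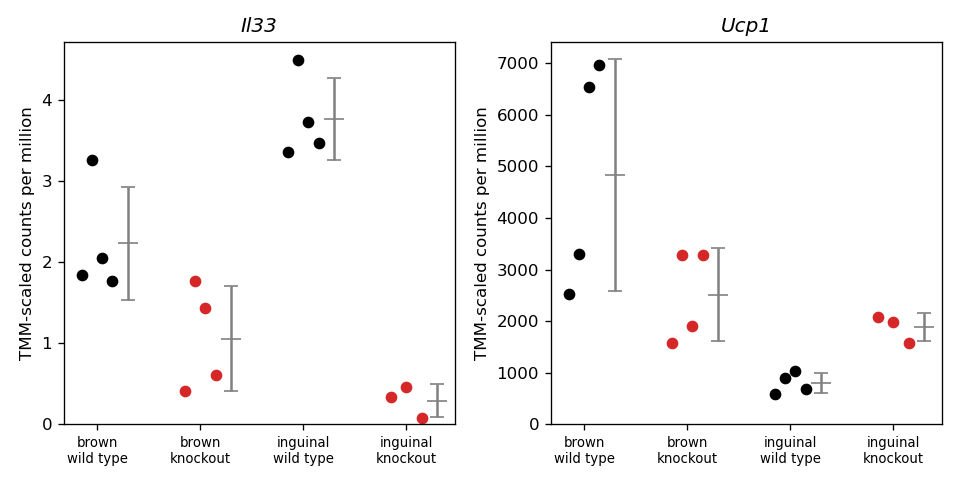
TMM-scaled CPM of Il33 (left) and Ucp1 (right) in each library, with group mean and SD as grey bars. The 3 inguinal knockout libraries lie below all inguinal wild-type libraries for Il33 and above them for Ucp1, while the brown groups overlap for Ucp1.

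In newborn brown fat the genes that rose included immediate early genes, which cells switch on within minutes of a stimulus. Fos, a subunit of the AP-1 transcription factor, rose from 2.58 ± 1.08 to 18.0 ± 2.53 CPM (SD, n = 4 each; log2 2.80, SE 0.29, edgeR adjusted p = 0.0122). Jun, its partner, rose by 1.86 (SE 0.20, edgeR adjusted p = 0.0128), and Junb and Zfp36, which encodes an mRNA-decay factor, by 1.70 and 1.62. Agpat2, an enzyme of triglyceride synthesis whose loss causes lipodystrophy, fell from 338 ± 80.3 to 96.2 ± 23.3 CPM (log2 -1.81, SE 0.21, edgeR adjusted p = 0.0167). Without wild-type library 2 the calls of Fos, Jun and Agpat2 were lost (0.0516, 0.0534 and 0.0534), without wild-type library 3 those of Jun and Agpat2 (0.0846 each), and that of Agpat2 without labelled knockout library 2 or 4 (0.0546 and 0.0811). With 1 library left out, Junb and Zfp36 passed only where it was labelled knockout library 1. In all, 41 of 15796 genes passed in brown tissue, 29 higher and 12 lower, and 2930 had an unadjusted p under 0.05.

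Other brown rises included Rgs1, a regulator of G-protein signalling (3.69), Klf15, a metabolic transcription factor (2.54), Maff (2.47), Errfi1, an inhibitor of EGF receptor signalling (2.17), Ccn1 (1.96), Ppp1r15a, a stress-induced phosphatase subunit (1.88), and Irf2bp2 (1.67). Rgs1 had 16 counts over the wild-type group. Other falls were Slc35g1 (-1.52), Grk3, a receptor kinase (-1.34), Pik3r3, a regulatory subunit of PI3-kinase (-1.21), Acot11, an acyl-CoA thioesterase (-1.13), the nucleoside transporter Slc28a2 (-0.78), Pabpn1 (-0.74) and Snn (-0.64). The edgeR adjusted p of the genes in this paragraph ran from 0.00813 for Irf2bp2 to 0.0496 for Acot11. Rgs1, Klf15, Errfi1, Ccn1, Ppp1r15a, Slc35g1, Acot11, Slc28a2, Pabpn1 and Snn lost the call without any 1 brown library other than labelled knockout library 1 (0.0505 to 0.171). Maff lost it without wild-type library 2 (0.0516), Grk3 without wild-type libraries 2 or 3 or labelled knockout libraries 2 or 4 (0.0516 to 0.115), and Pik3r3 without those or wild-type library 1 (0.0550 to 0.115). With no filter, Klf15, Errfi1, Ccn1 and Ppp1r15a no longer passed (0.0597 to 0.0866).

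Of 33 lists tested in brown tissue, 5 passed with camera, all upward. With fry 2 passed, the immediate early and heat shock and the endoplasmic reticulum stress lists (fry adjusted p = 0.0128 and 0.0437). The immediate early and heat shock list had 4 of 19 members higher, and 14 adjusted over the list alone (camera adjusted p = 1.29e-19, and adjusted p = 0.0510 with an estimated correlation). The extracellular matrix list had 0 of 26 members changed, and 0 adjusted over the list alone (camera adjusted p = 0.0179, and 0.855 as adjusted p with an estimated correlation); Col1a1, a collagen, had a log2 value of 0.79 with an edgeR adjusted p of 0.128, and passed with the DESeq2 Wald test (0.0166), limma-voom (0.0295) and all 4 groups in 1 fit (0.0316). The endoplasmic reticulum stress list had 0 of 18, and 2 higher adjusted over the list alone (camera adjusted p = 0.0321, adjusted p = 0.548 with an estimated correlation). The cholesterol synthesis list had 0 of 23, and 3 higher adjusted over the list alone (camera adjusted p = 0.0324, adjusted p = 0.713 with an estimated correlation). The adipose progenitor list had 0 of 14, and 1 higher adjusted over the list alone (camera adjusted p = 0.0395, adjusted p = 0.756 with an estimated correlation). For the 4 lists without a changed member, edgeR called 0 genes, and each list's call was lost without labelled knockout library 1 (camera adjusted p = 0.344 for matrix and for cholesterol, 0.314 for reticulum stress, 0.371 for progenitors). Leaving out wild-type library 1 ended the matrix and reticulum stress calls (0.0724 and 0.0516). Without wild-type library 3 the matrix, cholesterol and progenitor calls ended (0.0821, 0.0934 and 0.101), and without wild-type library 4 those of cholesterol and progenitors (0.0571 each).

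The other 28 lists did not pass in brown tissue, with camera adjusted p from 0.0809 to 0.989. The thermogenic list had 1 of 29 members lower, Acot11 (1 higher and 2 lower adjusted over the list alone). Otop1, a thermogenic-list ion channel, had a log2 value of -2.27 and an edgeR adjusted p of 0.0660. It passed with the DESeq2 Wald test (4.97e-07), limma-voom (0.0117) and all 4 groups in 1 fit (0.00342), and without labelled knockout library 1 (0.0135). The lipogenesis list had 1 of 24 lower, Agpat2 (3 higher and 2 lower alone), and the list of neighbours of Il33 had 1 of 17 higher, Uhrf2 (0.69, 1 higher alone). The calls of Acot11 and Uhrf2 were lost without any 1 library other than labelled knockout library 1. No member passed by edgeR over all genes in the endothelial, fatty acid oxidation, interferon, B-cell, lipolysis and storage, circadian, cell cycle, beige-selective, macrophage, epithelium, erythroid, sex-linked, alternative macrophage, cytotoxic, skeletal muscle, innate lymphoid type 2, neutrophil and mast cell, oxidative phosphorylation, eosinophil, adrenergic and neural, regulatory T-cell, IL-33 signalling, splicing, T-cell and white adipocyte lists. Adjusted over the list alone, members passed in the circadian list (5 higher, 1 lower), fatty acid oxidation (2 lower), innate lymphoid type 2 (2 higher, 1 lower), splicing (2 lower), and 1 each in the macrophage, sex-linked, adrenergic and IL-33 signalling lists. The median and the test had opposite signs for oxidative phosphorylation, neighbours of Il33, splicing and white adipocyte genes, and the mean and the test for splicing and white adipocyte genes.

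The brown count depended on single libraries: it was 10, 2, 3 and 15 without wild-type libraries 1 to 4, and 2905, 8, 19 and 5 without labelled knockout libraries 1 to 4. It was 1032 with the DESeq2 Wald test, 3094 with limma-voom, 1151 with all 4 groups in 1 fit and 67 with no filter on low counts. On the component holding 42.1% of the brown variance, labelled knockout libraries 2, 3 and 4 lay at 49.5, 24.8 and 51.4. Labelled knockout library 1 lay at -37.0, on the side of the wild-type libraries (-26.6 to -19.3) but beyond them. On the next component (20.85%) it lay at 46.5, above all other brown libraries (-36.85 to 9.38). The mitochondrial-like pseudogenes took 10.7 ± 1.17% of counts in wild-type and 8.82 ± 0.51% in labelled knockout brown libraries (SD, n = 4 each; two-sided exact permutation p = 0.0286, the smallest possible).

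**Figure D2:**
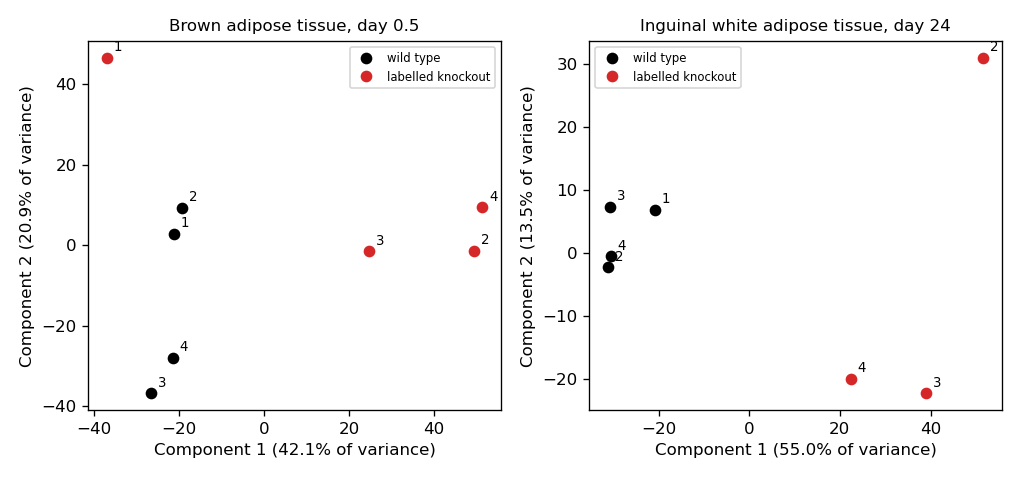
Positions of the libraries on the leading pair of principal components of log2 CPM of all tested genes, for brown (left) and inguinal tissue (right), with replicate numbers beside the points. Labelled knockout library 1 lies at -37.0 on the horizontal and at 46.5 on the vertical brown axis. The inguinal genotypes separate along the horizontal axis that holds 55.0% of the variance.

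In inguinal fat of day 24, 4498 of 15710 genes passed, 2410 higher and 2088 lower. How far this count exceeded the brown count depended on the setting: limma-voom called 4059 genes in inguinal and 3094 in brown tissue, and edgeR called 2905 brown genes without labelled knockout library 1. Elovl3, a fatty acid elongase induced in cold-exposed fat, rose from 4.04 ± 2.06 (SD, n = 4) to 78.0 ± 21.7 CPM (n = 3; log2 4.31, SE 0.40, edgeR adjusted p = 0.000532). Cyp2b10, a cytochrome P450 enzyme, rose from 0.292 ± 0.0662 to 43.9 ± 8.31 CPM (log2 7.23, SE 0.19, edgeR adjusted p = 1.31e-11). Myh4, a fast-muscle myosin, fell from 52.4 ± 32.1 to 3.83 ± 1.20 CPM (log2 -3.75, SE 0.68, edgeR adjusted p = 0.0113).

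Further inguinal rises were Fgf21, a metabolic hormone (5.22, with 4 counts over the wild-type group), Mab21l2 (4.54), the organic anion transporter Slco4a1 (4.07), Acot12, an acetyl-CoA thioesterase (3.95), Grip1 (3.76), Sptlc3, a subunit of serine palmitoyltransferase (3.48), and the clock activators Npas2 (3.41) and Arntl (3.39). Arntl rose from 2.57 ± 0.224 to 27.0 ± 5.02 CPM (SD, n = 4 and 3; SE 0.15, edgeR adjusted p = 8.01e-09). The other largest falls were muscle genes: Mylk4 (-4.27), Actc1 (-4.11), Tcap (-3.08), Pvalb (-2.99), Actn3 (-2.97), Mybpc2 (-2.95), Trdn (-2.78) and Ryr1 (-2.76). Low counts make the size of some of these rises and falls uncertain. Over the wild-type group Mab21l2 had 12 counts, Acot12 13, Sptlc3 21 and Grip1 24. Over the knockout group Mylk4 had 7 counts, Tcap 14 and Actc1 20. The call of Actc1 (SE 1.02, edgeR adjusted p = 0.0235) was lost without knockout library 2, 3 or 4 (0.0872, 0.0761 and 0.0791) or without a filter (0.0713), and that of Myh4 without knockout library 2 (0.0576). With limma-voom, Actc1, Myh4, Pvalb, Actn3, Mybpc2, Trdn and Ryr1 did not pass (adjusted p from 0.0624 to 0.266).

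Of 31 lists tested in inguinal tissue, 14 passed with camera, 7 upward and 7 downward, and 0 with an estimated correlation. By fry 10 were called, and 15 had an unadjusted camera p under 0.05. The skeletal muscle list passed with fry (fry adjusted p = 0.0241) and the B-cell list did not (fry adjusted p = 0.106). The skeletal muscle list had 17 of 23 members lower (1 higher and 18 lower adjusted over the list alone; camera adjusted p = 1.05e-15, adjusted p = 0.299 with an estimated correlation). The B-cell list had 4 of 18 lower (0 adjusted over the list alone; camera adjusted p = 0.00139, adjusted p = 0.755 with an estimated correlation). Fcmr, a receptor for IgM, fell by 1.28 (edgeR adjusted p = 0.0205), a call lost without wild-type library 2 or knockout libraries 2 or 3 (0.0619, 0.0693 and 0.0717). Muscle and B-cell transcripts thus differed between the same libraries as every inguinal gene group given here. The share of counts in mitochondrial-like pseudogenes was 7.85 ± 0.54% in wild type (SD, n = 4) and 6.49 ± 0.78% in knockout (n = 3; two-sided exact permutation p = 0.0571, the smallest possible being 0.0286). Benjamini-Hochberg adjustment over the 2 depots gave 0.0571 for each.

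The metabolic lists in this paragraph were higher with camera and did not pass with an estimated correlation. With fry, fatty acid oxidation, lipogenesis and the thermogenic list passed (fry adjusted p = 0.0241, 0.0282 and 0.0473). Cholesterol synthesis and oxidative phosphorylation did not (fry adjusted p = 0.106 and 0.0869). The lipolysis and storage list did not pass (camera adjusted p = 0.662). In fatty acid oxidation, 18 of 28 members rose and 1 fell (18 and 2 adjusted over the list alone; camera adjusted p = 6.15e-10, adjusted p = 0.591 with an estimated correlation). Acsl5, which activates fatty acids, rose by 1.63 and Acadm, a mitochondrial dehydrogenase, by 0.97. In lipogenesis, 14 of 24 rose and 1 fell (18 and 2 alone; camera adjusted p = 1.07e-07, adjusted p = 0.591 with an estimated correlation), with Scd2 at 1.19 and Acly, which makes cytosolic acetyl-CoA, at 0.97. In the thermogenic list, 14 of 29 rose and 5 fell (19 and 5 alone; camera adjusted p = 1.19e-05, adjusted p = 0.591 with an estimated correlation). Letmd1 rose by 1.21 and Pank1, a kinase of coenzyme A synthesis, by 0.90, while Adrb3, the adrenergic receptor of adipocytes, fell by 0.75. In cholesterol synthesis, 8 of 23 rose and 0 fell (9 and 0 alone; camera adjusted p = 0.00348, adjusted p = 0.823 with an estimated correlation), Lss among them at 0.93. In oxidative phosphorylation, 21 of 76 rose and 3 fell (22 and 3 alone; camera adjusted p = 0.0151, adjusted p = 0.825 with an estimated correlation), Ndufs1 of complex I among them at 0.62. That list's call ended without knockout library 2 (camera adjusted p = 0.122). Muscle and B-cell lists were lower in the same libraries.

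Lists of proliferation, immunity and vessels moved as follows, again beside lower muscle and B-cell lists. With fry the interferon, neutrophil and mast cell, endothelial and white adipocyte lists passed (fry adjusted p from 0.0016 to 0.0473). The cell cycle and splicing lists did not (fry adjusted p = 0.057 and 0.125). In the cell cycle list, 24 of 28 fell and 0 rose (25 and 0 alone; camera adjusted p = 1.27e-09, adjusted p = 0.591 with an estimated correlation), with the replication helicase subunit Mcm6 at -0.67 and cyclin A2, Ccna2, at -0.88. In the interferon list, 16 of 28 fell and 1 rose (17 and 1 alone; camera adjusted p = 2.78e-07, adjusted p = 0.591 with an estimated correlation), with the chemokine Cxcl9 at -1.59 and Ifit3 at -1.28. In the neutrophil and mast cell list, 7 of 12 rose and 0 fell (8 and 0 alone; camera adjusted p = 2.78e-07, adjusted p = 0.199 with an estimated correlation). Its examples Cpa3 (1.44) and Mcpt4 (1.07) are mast cell proteases. In the endothelial list, 8 of 15 fell and 0 rose (10 and 0 alone; camera adjusted p = 0.000643, adjusted p = 0.591 with an estimated correlation), among them the junction genes Esam (-0.57) and Cldn5 (-0.77). In the white adipocyte list, 2 of 16 rose and 5 fell (2 and 7 alone; camera adjusted p = 0.00892, adjusted p = 0.591 with an estimated correlation), Nnat at -1.98 and Agt, angiotensinogen, at 1.44. In the splicing list, 10 of 51 fell and 2 rose (10 and 2 alone; camera adjusted p = 0.0250, adjusted p = 0.83 with an estimated correlation), Tra2a at -0.68. The splicing call ended without wild-type library 4 (0.0975) or knockout library 2 (0.152).

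Genes taken to lie near Il33 formed a fixed list, as a knockout made by gene targeting can carry flanking DNA of another strain. One member, Kdm4c, lies on another chromosome in the mouse and did not pass. Of 18 tested, 9 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.00563, adjusted p = 0.591 with an estimated correlation). With fry this list passed (fry adjusted p = 0.0206). Cd274, which encodes the checkpoint ligand PD-L1, rose by 0.99 and Rcl1 by 0.59.

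The circadian list did not pass as a set (camera adjusted p = 0.662), its members going both ways: 7 of 18 rose and 8 fell (7 and 8 alone). Dbp, an output gene of the clock, fell by 2.72 (SE 0.15, edgeR adjusted p = 2.26e-07), and Nfil3, a repressor, rose by 1.99. Other lists did not pass either, with camera adjusted p from 0.0948 to 0.969. Of these, the epithelium list passed with fry (fry adjusted p = 0.0386). The counts higher and lower were 0 and 2 of 8 for epithelium (Cdh1, E-cadherin, at -1.58), 1 and 5 of 26 for extracellular matrix, 0 and 3 of 18 for macrophages, and 3 and 6 of 15 for adrenergic and neural genes (S100b at 1.42). They were 3 and 5 of 19 for immediate early genes, Junb at 1.24, 4 and 3 of 14 for beige-selective genes, P2rx5 at 0.87 and Tmem26 at -0.93, and 6 and 5 of 20 for lipolysis and storage. They were 3 and 3 of 18 for reticulum stress (Trib3 at 2.18), 1 and 3 of 14 for adipose progenitors, 1 and 2 of 15 for alternative macrophages, 1 and 0 of 9 for regulatory T cells, and 2 and 3 of 14 for IL-33 signalling. By edgeR, 0 members passed of 6 cytotoxic, 11 innate lymphoid type 2, 13 erythroid and 20 T-cell genes. The eosinophil and sex-linked lists had under 5 tested members. The beige-selective and reticulum stress tests ran upward with a negative median, the IL-33 signalling test upward with a negative mean, the circadian test downward with a positive mean, and the T-cell test downward with positive median and mean.

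The inguinal count was 2249 with all 4 groups in 1 fit. In that fit Pank1, Scd2, Acly, Ccna2, Fcmr, Cldn5, Rcl1, Adrb3, Cdh1, P2rx5 and Tmem26 no longer passed, with adjusted p from 0.0518 for Pank1 to 0.401 for Adrb3.

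**Figure D3:**
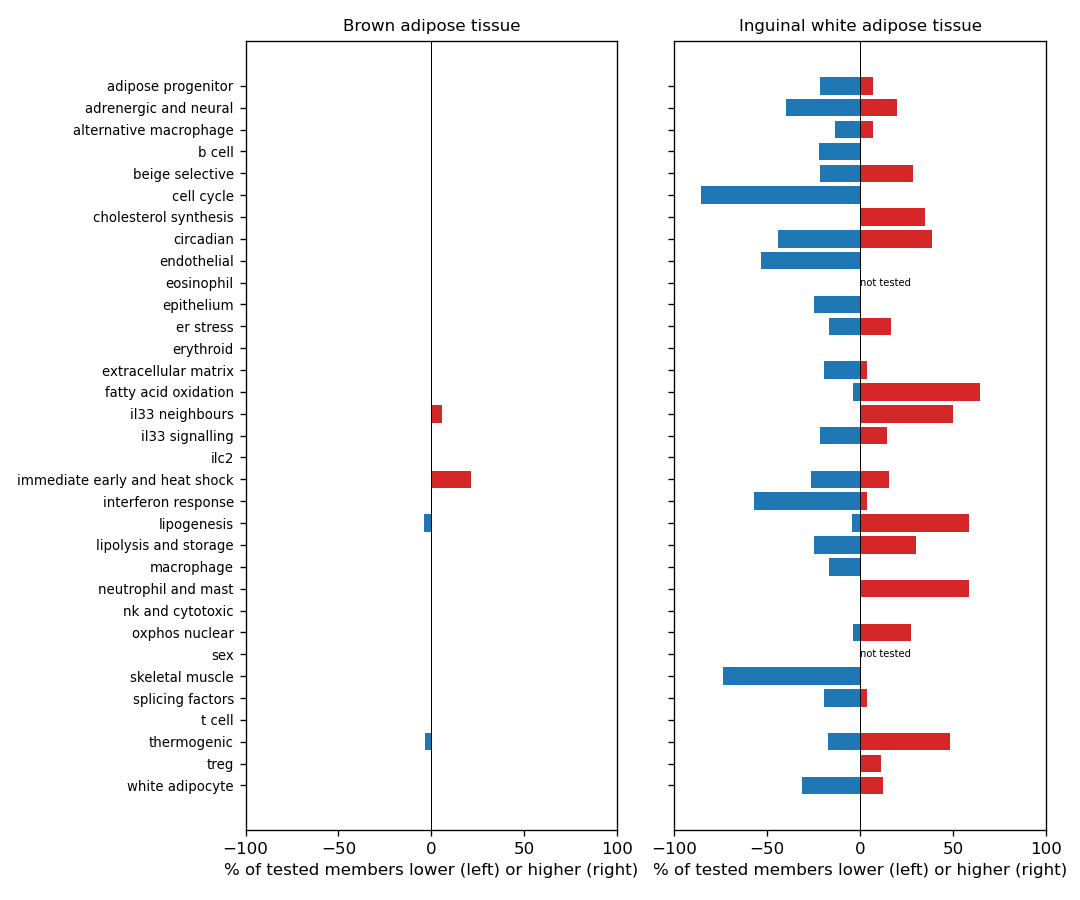
Percent of the tested members of each gene list that passed the edgeR test, higher (red, right) or lower (blue, left) in knockout than in wild type. Brown tissue has calls in 4 lists, and in inguinal tissue 24 of 28 cell cycle members are lower and 18 of 28 fatty acid oxidation members higher.

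**Figure D4:**
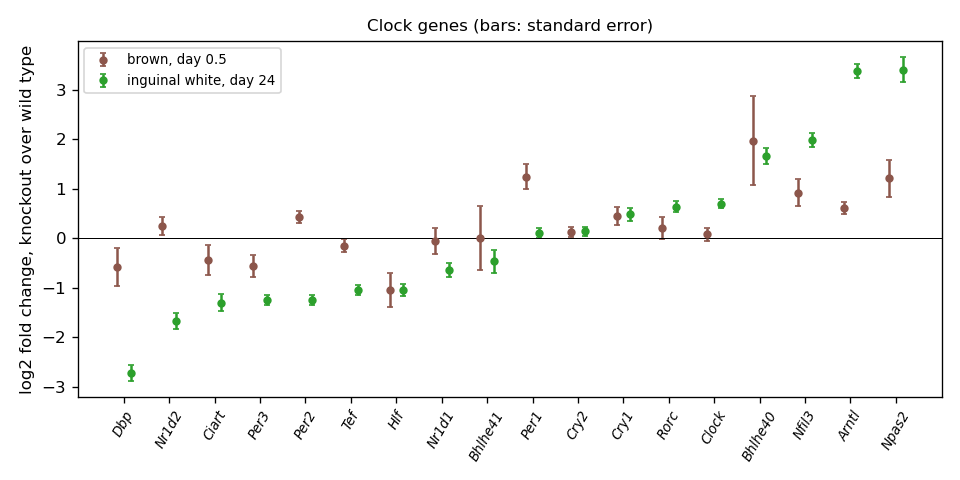
Log2 fold change, labelled knockout over wild type, with its standard error, of the 18 circadian list members in brown (brown points) and inguinal tissue (green points). In inguinal tissue Arntl is at 3.39 and Dbp at -2.72.

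The effect of the knockout label differed between the depots for 1517 of 16858 genes, 809 more positive and 708 more negative in inguinal than in brown tissue. The difference was 5.56 (SE 0.83, edgeR adjusted p = 0.00214) for Elovl3, 5.93 (SE 0.87) for Mab21l2 and 7.59 (SE 1.34) for Acot12. Irf4, a transcription factor of thermogenic fat and of immune cells, stood at 95.9 ± 49.4 and 1226 ± 1001 CPM in wild-type and labelled knockout brown tissue (SD, n = 4 each) and at 182 ± 123 (n = 4) and 32.0 ± 3.18 CPM (n = 3) in inguinal tissue. Its difference was -6.18 (SE 1.37, edgeR adjusted p = 0.0171), and the call was lost without inguinal knockout library 2 (0.0525) or 3 (0.0624). Of 33 lists, 9 passed for the difference, 3 upward and 6 downward, and 0 with an estimated correlation, while fry called 8 and 14 had an unadjusted camera p under 0.05. Lists for muscle and interferon differed downward, 12 of 24 and 12 of 28 members being more negative in inguinal tissue (camera adjusted p = 1.80e-16 and 1.82e-08). Fatty acid oxidation differed upward, with 13 of 28 members more positive (camera adjusted p = 5.47e-13). With an estimated correlation the adjusted p of these lists was 0.131, 0.275 and 0.131. The thermogenic list differed upward, with 7 of 31 members more positive and 1 more negative (camera adjusted p = 5.12e-05, adjusted p = 0.131 with an estimated correlation). The immediate early list differed downward, with 7 of 19 members more negative (camera adjusted p = 5.41e-10, adjusted p = 0.0782 with an estimated correlation). The other 4 were cell cycle, epithelium and extracellular matrix downward, with 4 of 28, 1 of 15 and 1 of 26 members, and neutrophil and mast cell genes upward, with 2 of 17. Their camera adjusted p ran from 1.11e-05 to 0.0109, and from 0.140 to 0.632 with an estimated correlation. The epithelium list had a median difference of -4.75, and 10 members were more negative adjusted over the list alone (fry adjusted p = 0.118). The cause was not tested.

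Cyp2b10 differed by 5.44 (SE 1.34, edgeR adjusted p = 0.0254) and Il33 by -2.65 (SE 0.66, edgeR adjusted p = 0.0218). The Cyp2b10 call was lost without any inguinal library except knockout library 4 (0.0531 to 0.0630). It was also lost with limma-voom (0.0515), without a filter (0.0607) and with the replicate number as a block (0.124). The Il33 call was lost without inguinal knockout library 2 (0.0529) or 4 (0.0501). Il1rl1 differed by 0.07 (SE 0.32, edgeR adjusted p = 0.921). The count of 1517 rose to 3571 without brown labelled knockout library 1 and fell to 632 without inguinal knockout library 3. It was 1011 without brown wild-type library 4, 992 without brown labelled knockout library 4, 969, 967 and 980 without inguinal wild-type libraries 2, 3 and 4, and 818 without inguinal knockout library 2. The DESeq2 Wald test gave 2351 and limma-voom 3652.

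Few genes were called in both depots. Of 15051 genes tested in both, 8 rose in both, among them Junb, Klf15 and Ppp1r15a, where independent lists would share 4.57 (one-sided Fisher exact p = 0.0739). Another 3 fell in both, Slc28a2 and Snn among them, against 1.45 (p = 0.169, one-sided Fisher exact test). Fos, Jun, Ccn1, Agpat2, Acot11 and Grk3 were among 8 genes called in opposite directions. Across genes, which are not independent replicates, the fold changes had Pearson r = 0.0219 and Spearman rho = 0.0391. The 11 shared calls became 2, 0, 0 and 5 without brown wild-type libraries 1 to 4, and 491, 2, 6 and 1 without brown labelled knockout libraries 1 to 4. At an unadjusted p under 0.01 the shared count was 188. The count of 491 came with 2905 brown calls. No number expected for independent lists was computed for 491 or 188, so neither shows sharing beyond chance.

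Wild-type brown and inguinal tissue differed at 9814 of 15979 genes, 4910 higher in brown and 4904 higher in inguinal tissue. Ucp1 was higher in brown, 4810 ± 2213 against 835 ± 208 CPM (SD, n = 4 each; log2 2.53, SE 0.38, edgeR adjusted p = 0.000625), as was Il1rl1 (1.87, SE 0.24, edgeR adjusted p = 5.78e-05). Il33 was lower in brown by a log2 value of -0.82 (SE 0.22, edgeR adjusted p = 0.00580), a call lost with all 4 groups in 1 fit (0.0889). The posterior patterning gene Hoxc10 (-9.68) and Retnla, a product of alternatively activated macrophages (-8.91), were lower in brown tissue, with 4 and 17 counts over the brown wild-type group. Irs4, an insulin receptor substrate, stood at 10.2 ± 3.69 CPM in brown and had 3 counts over the inguinal wild-type group. Vgll2 and Chrng, genes of developing muscle, stood at 1.81 ± 0.684 and 2.20 ± 1.36 CPM in brown tissue and had 0 counts in inguinal wild type. Skeletal muscle, neutrophil and mast cell and oxidative phosphorylation lists were higher in brown, with 22 of 24, 14 of 15 and 62 of 76 members (camera adjusted p = 4.08e-23, 3.11e-14 and 1.85e-09). White adipocyte, cholesterol and B-cell lists were lower, with 13 of 16, 19 of 23 and 16 of 18 members (camera adjusted p = 4.38e-16, 3.05e-12 and 1.20e-06). Of 33 lists 21 passed, and 0 with an estimated correlation, where the adjusted p of these 6 ran from 0.0510 to 0.415. With fry 29 of the 33 passed.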

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

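The tests of a different collection hour, of brown labelled knockout library 1 and of the DNA around Il33 were chosen after the result was seen, as was the position of each left-out library, and the tests of strain DNA and of Il33 in that library were rewritten after their values had been seen. The splits of the libraries and the test of clock genes without each library were planned. These 3 patterns were picked for weighing after the results were seen.

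In inguinal tissue 15 of 18 clock genes passed, with Arntl and Npas2 higher and Dbp lower in knockout. A single library does not account for it, since at least 14 of the 15 were called again without any one library. A candidate explanation is a different hour of tissue collection for the 2 genotypes: 100% of the called genes with a textbook phase, 13 of 13, moved as a shift of phase would move them. The direction of the shift was taken from these same genes, so an outcome against this explanation was not possible. The phase score of the wild-type libraries spread over 14.9% of the group difference of 3.10 log2 units, so no spread of hours within a group helps to test it. Collection hour and an effect of the genotype on the clock cannot be told apart, because the labels give no hour and all knockout libraries moved together.

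Brown labelled knockout library 1 lay at -37.0 on the leading component, on the side of the wild-type libraries (-26.6 to -19.3) but beyond them. The other 3 labelled knockout libraries lay at 24.8 to 51.4. On the next component, with 20.85% of the variance, the wild-type libraries lay at -36.85 to 9.29 and the other labelled knockout libraries at -1.59 to 9.38. Labelled knockout library 1 lay apart from both, at 46.5. Its Il33 level of 0.438 CPM (exact interval 0.245 to 0.722) was below the lowest wild-type brown library (1.77). With the spread of log2 values pooled over the brown groups, a further wild-type library is predicted at 0.541 CPM or more, a bound inside that interval. The pooled spread (SD 0.736) includes this library itself, and the SD was 0.427 in wild-type and 0.949 in labelled knockout libraries. The bound thus rests in part on the library it is meant to judge, so Il33 does not decide. Fos (18.6 CPM), Jun (83.7) and Wdfy1 (93.1) were above all wild-type libraries in it, but these genes were picked with it counted as knockout. Over the 50 genes of smallest p in the fit without it, its median position was 0.0679 between the wild-type mean at 0 and the labelled knockout mean at 1, where the same measure gave 0.0427 to 0.251 for the wild-type and 0.668 to 1.07 for the other 3 labelled knockout libraries. A wild-type library under a knockout label and a knockout library that resembled wild type over these 50 genes thus cannot be told apart. Its total count was 97.9% of the brown median, which argues against shallow sequencing. The labels give no group that would part it from the others, so no biological explanation was tested, and feeding, litter or dissection stay open.

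In the inguinal comparison 25 of the 50 tested genes nearest to Il33 passed, 15 higher and 10 lower, a share reached by 0.270% of 14096 windows of that size, whose median was 30%. DNA of another strain carried along with the deleted allele and acting alike in both depots is argued against as the cause of this share. Of the 24 passing genes tested in brown tissue, 29.2% (7, exact interval 12.6 to 51.1%) had the same sign there, against 52.0% of all inguinal calls. The opposite sign with a difference between depots was found for 54.2% (13), against 22.7% of all inguinal calls. Given the brown standard errors, a shared effect would give 99.2%, and 68.7% if only the genes beyond the median window shared it, at 0.5 of its size. Neighbouring genes are not independent, but with the 4 Ifit genes counted once the interval still ended at 57%. The reading takes the brown labels as given, which Il33 does not settle. DNA of another strain that acts differently by tissue and an effect of the knockout cannot be told apart, because both go with the genotype label. In brown tissue 2% of the window passed, a share reached by 11.7% of windows, so the brown calls were too few to decide. Groups from C57BL/6 substrains that differ at Nnt are argued against, as the log2 change of Nnt was 0.066 (interval -0.37 to 0.50). The effect of losing IL-33 on these genes was not tested separately.

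Of 116 groups of 4 libraries tested, 4 held a library far from the others, where chance gives about 1 in 20. Rgs1 was 0.275 CPM in brown wild-type library 2 against 0.0479 to 0.0827 in the others. Jun was 83.7 CPM in brown labelled knockout library 1 against 48.1 to 51.7. Cyp51 was 27.0 CPM in brown wild-type library 2 against 16.8 to 17.9. Nnat was 662 CPM in inguinal wild-type library 2 against 590 to 598.

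The knockout effect differed between depots for 1517 genes, and for 52 of the 80 named genes tested, by the edgeR test of the difference itself. Values here are inguinal minus brown log2 changes. Positive differences above 2 were Acot12 7.59, Fgf21 6.53, Mab21l2 5.93, Elovl3 5.56, Cyp2b10 5.44, Slco4a1 4.97, Grip1 4.06, Acot11 3.71, Arntl 2.75, Otop1 2.60, Grk3 2.37, Agpat2 2.22, Npas2 2.17 and Ucp1 2.15. Fgf21 had 2 counts over the brown labelled knockout group, so its value rests on the prior count of the fit. Acot12 had 14 counts over that group and 13 over the inguinal wild-type group. Smaller positive differences were Acsl5 1.69, Cd274 1.62, Slc35g1 1.5, Letmd1 1.31, S100b 1.30, Trib3 1.22, Acadm 1.21, Pik3r3 1.17, Pabpn1 0.73 and Ndufs1 0.67.

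Negative differences of metabolic, immune and regulatory genes were Pdia6 -0.54, Esam -0.69, Mcm6 -0.82, Uhrf2 -0.84, Tra2a -1.10, Zfp36 -1.36, Ifit3 -1.64, Irf2bp2 -1.65, Nnat -2.03, Cxcl9 -2.07, Dbp -2.17, Maff -2.23, Klf15 -2.30, Jun -2.38, Errfi1 -2.41, Il33 -2.65, Ccn1 -2.92, Rgs1 -3.44, Fos -3.57 and Irf4 -6.18. Muscle genes differed by -2.34 for Trdn, -2.60 for Ryr1, -3.06 for Actn3, -3.21 for Mybpc2, -3.30 for Tcap, -3.43 for Pvalb, -3.55 for Myh4 and -4.35 for Mylk4.

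Each count was set beside the counts from other splits of the same libraries. In brown tissue 1 of 35 splits, the real one, called as many as 41 genes, and the highest other called 0. In inguinal tissue 1 of 35 called as many as 4498, and the highest other called 11. For the difference between depots 1 of 100 drawn splits called as many as 1517, the highest other calling 590. For wild-type tissues 1 of 35 called as many as 9814, and the highest other called 0. The real split thus called the most genes for each of these 4 counts. Splits that mix the real groups widen the spread within groups, which lowers their counts, so the ranking does not exclude chance. For wild-type tissues this outcome was foreseeable. As the labels do not say that libraries came from separate animals, the splits do not bear on chance between animals.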

How the results depend on the processing

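Removing the mitochondrial-like pseudogenes was tried after seeing the data and moved no count by over 1.5 times. The other alternatives were planned, and all were run. Il33 and Ucp1 kept direction and side of the threshold in each depot under every alternative checked for single genes. The filter at 5 CPM, non-robust dispersions and the removal of pseudogenes were checked for counts of genes only. The inguinal count stayed between 3274 and 4719 without any library, and the tissue count between 9106 and 9950. The inguinal count was 2249 with all 4 groups in 1 fit. The brown count was 67 with no filter, 1032 with the DESeq2 Wald test, 3094 with limma-voom and 1151 with all 4 groups in 1 fit, and ran from 2 (without wild-type library 2) to 2905 (without labelled knockout library 1). Of the 41 brown genes, 41 were called again in that last setting and 1 to 13 without any other library, with 0 changes of sign. The count of differing effects was 2351 with the Wald test and 3652 with limma-voom, and ran from 632 to 3571 without a library. Shared calls were 188 at an unadjusted p under 0.01 and ran from 0 to 491, with no expected number computed for these settings. Passing lists were 0 in each depot with an estimated correlation, and in brown tissue 2 with fry and from 1 to 11 without a library. The Il1rl1 difference, not called, ran from -0.16 to 0.23 without a library. The cause of these changes was not tested.

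The labels number the libraries and do not say that a number marks anything shared. Correlations of same-numbered libraries were 0.0934, -0.0398, 0.174 and 0.0992 in brown and -0.0992, -0.0393 and 0.0465 in inguinal tissue, with 1 of the 7 over 0.1. In brown tissue 6 of 8 libraries correlated best with their own number, and in inguinal tissue 0 of 6. The brown value leaves a pairing by number open there, and the inguinal value does not bear on it. The main fits did not pair the libraries. With the replicate number as a block the brown count was 7, the count of differing effects 864, shared calls 0, brown lists 8 and the Il1rl1 difference -0.068. The block ended 16 gene calls: Klf15, Ccn1, Ppp1r15a, Jun, Junb, Agpat2, Slc35g1, Pik3r3, Acot11, Slc28a2, Pabpn1, Snn, Uhrf2 and Wdfy1 in brown tissue, Myh4 in inguinal tissue and Cyp2b10 for the difference.

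Of results for the genes picked for the text, including Gdf10 and Cpt1a that the report does not give, leaving out a library kept 642, ended 128 calls, added 6 and reversed 4, all 4 for Il1rl1. Calls ended 12 times with all 4 groups in 1 fit, 8 with limma-voom and 6 with no filter. The DESeq2 Wald test, limma-voom and the fit of all 4 groups each added 7 in brown tissue: Otop1, Col1a1, Cyp51, Pdia6, Gdf10, Arntl and Cpt1a. All of them but Col1a1 were the 6 added without labelled knockout library 1.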

Other observations

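The genes in this part were chosen after their values were seen. Wdfy1, an endosomal adaptor, rose in both depots: from 31.1 ± 2.36 to 85.6 ± 21.3 CPM in brown tissue (SD, n = 4 each; log2 1.46, SE 0.17, edgeR adjusted p = 0.0167) and from 23.7 ± 0.520 (n = 4) to 44.6 ± 12.3 CPM (n = 3) in inguinal tissue (log2 0.92, SE 0.14, edgeR adjusted p = 0.000467). It was higher in each knockout library than in any wild-type library of its depot. The brown call was lost without wild-type library 1, 2 or 3 (edgeR adjusted p = 0.0550, 0.0616 and 0.0845) and with the replicate number as a block (0.0621).

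Irf4, Lpin1 and Cyp2b10 varied between the brown labelled knockout libraries more than between the wild-type ones. Irf4 stood at 47.0, 1990, 766 and 2180 CPM in labelled knockout libraries 1 to 4 and at 31.5 to 151 CPM in wild type (log2 3.67, SE 0.97, edgeR adjusted p = 0.122). Lpin1, a phosphatidate phosphatase, stood at 687, 2687, 2083 and 2228 CPM against 453 to 580 CPM (log2 1.86, SE 0.35, edgeR adjusted p = 0.0695). Cyp2b10 stood at 0.390, 46.6, 15.7 and 25.7 CPM against 1.65 to 8.91 CPM (log2 1.77, SE 0.96, edgeR adjusted p = 0.355). Pck1, which makes the glycerol backbone of triglycerides, stood at 1340, 6350, 5001 and 6447 CPM, and at 1426 to 5033 CPM in wild type (log2 0.66, SE 0.54, edgeR adjusted p = 0.547). In inguinal tissue Lpin1 rose by 0.62 (SE 0.10, edgeR adjusted p = 0.000694) and Pck1 fell by 0.58 (SE 0.16, edgeR adjusted p = 0.0132), while the value of Irf4, -2.49 (SE 0.72), did not pass (edgeR adjusted p = 0.0507).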
